A study of Homo sapiens with 18 samples.

How the data were processed

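The assay measured how fast each member of a pool of precursor microRNAs (pre-miRNAs) was lost to cleavage by DICER, the ribonuclease III enzyme that cuts hairpin precursors into short duplexes. Pools carried random bases on both strands of the stem of human let-7a-1 or miR-374b, so that each randomised position holds 1 of 16 base pair states. The input pool and the uncleaved pool left after a labelled percentage of cleavage were each sequenced. Per the labels' protocols, the RNAs went through AQ-seq, a small RNA sequencing method built to lower ligation bias, with gel purification, 3' adapter ligation, reverse transcription and PCR, and were read on a NovaSeq instrument.

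Each of the 18 deposited tables holds the authors' raw read counts per sequence variant, with no normalization, as the values show: they are whole numbers with a different total in each library, and the headers name only the library. Per the submitters' processing notes, cutadapt was used; its version, the rule that assigned reads to variants and any collapsing of PCR copies are not given in the sources used here. PCR copies and sequencing errors that turn an abundant variant into a neighbour would both act on these counts. Intervals therefore cover counting error only.

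Libraries were grouped by backbone, randomised positions and cleavage level from the labels, which gave 5 series. Positions -1 to 1 and positions 1 to 3 were randomised in both backbones, with an input and uncleaved pools after 10, 20 and 30% cleavage. Positions -1 to 3 were randomised in let-7a-1 only, with an input and an uncleaved pool after 5% cleavage. Every library was the only one of its group, so no comparison had replicates. The 3 levels of a series share 1 input, and the labels do not say whether the levels were separate reactions.

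A variant is written as 2 strings joined by a slash. The first was read as the 5p strand and the second as the 3p strand, each from its 5' end; which string is which strand is a convention, since the files do not state it. The register was checked on the data. Pairing the first base with the last gave pairwise interaction sums of 0.256, 0.690, 0.0554, 0.145 and 0.0181 in the let-7a-1 and miR-374b -1 to 1 series, the let-7a-1 and miR-374b 1 to 3 series and the -1 to 3 series. Pairing the first base with the first gave 0.0555, 0.167, 0.0347, 0.0829 and 0.00166 in the same order. Position -1 was taken as the last base of the first string with the first base of the second. With that end, the 48 pair effects of the -1 to 3 series correlated with those of the let-7a-1 -1 to 1 series at r = 0.892, against 0.249 with the opposite end. For the let-7a-1 1 to 3 series the values were 0.659 and 0.461. Pairs are written with the 5p base first, so C-G is a 5p C opposite a 3p G.

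The depletion score of a variant is log2 of its share in the input over its share in the uncleaved pool, with 0.5 counts added to each. A positive score means that the variant was lost from the uncleaved pool faster than the pool average. Scores are relative to the pool, so a negative score is slower than average and not an absence of cleavage. Each score has an exact Clopper-Pearson 95% interval from the split of the variant's reads between the 2 libraries. Variants with fewer than 100 input reads were left out of the series with 3 random pairs (58 in let-7a-1 -1 to 1, 21 in miR-374b -1 to 1, 45 in let-7a-1 1 to 3 and 13 in miR-374b 1 to 3), and those with fewer than 20 out of the -1 to 3 series (249685). The median input reads per variant were 551, 1650, 477 and 1932 in the same order and 37 in the -1 to 3 series. For a variant with 0 uncleaved reads the lower bound of this interval is given, since its score rests on the added 0.5 counts.

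Calls in the 4 series with 3 levels came from edgeR's quasi-likelihood test, two-sided, of counts on exposure, taken as -ln(1 - f) with f the labelled cleaved fraction and 0 for the input. Library sizes were total counts, and p-values were adjusted by Benjamini-Hochberg at 0.05. Each fit held 4 libraries and left 2 residual degrees of freedom, so its p-values measure the scatter of single libraries around a line, which may be technical. The line rests on the labelled percentages, so this scatter also holds any error in those labels. edgeR estimates that scatter with information from all variants of the series, so very small p-values come from pooled spread and depth, not from replicates. The fitted depletion is the log2 loss of share at the exposure of the 30% library. Its SE was derived as its absolute value over the square root of the test's F statistic. Differences between backbones came from the backbone by exposure term over the 8 libraries of a region, with SE derived in the same way. They come from that joint fit and need not equal the difference of the separate fits. The -1 to 3 series has 1 input and 1 level, so it has values and no test. Classes of variants were compared with 10000 random lists of the same size matched on input reads in 10 bins. Sequence models were least squares fits on the mean score with 5-fold cross-validation. Correlations are across variants, which are not independent replicates, with 95% intervals from 1000 bootstrap resamples of variants.

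Named variants were chosen by a rule fixed before the data were examined. In each series with 3 levels they were the 10 with the largest and the 10 with the smallest fitted depletion among those past the threshold with the same sign at all 3 levels. In the -1 to 3 series they were the 10 highest and 10 lowest by the interval bound nearest 0. At each position the highest and lowest of the 16 pair states were named. The classes were fixed at the same time. The GYM classes came from background knowledge of the field and were not chosen from the counts used here. Whether that knowledge itself rests on these libraries was not checked, so the GYM scores are no independent test of GYM. Watson-Crick pairs are A-U, U-A, G-C and C-G, wobble pairs are G-U and U-G, and every other pair is a mismatch. The GYM classes hold a G in a Watson-Crick pair at -1, a pyrimidine in a Watson-Crick pair at 0 and a mismatched A or C at 1, all on the 5p or all on the 3p strand, with further classes that lack each element in turn.

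The trend test was run on simulated counts for the real variants with 200 changed. At a true log2 depletion of 0.5 it recovered 75.5% in let-7a-1 -1 to 1, 94.0% in miR-374b -1 to 1, 76.0% in let-7a-1 1 to 3 and 98.0% in miR-374b 1 to 3. At a depletion of 1 it recovered 98.0, 100, 100 and 100% in that order. It called 0.0522, 0.155, 0.338 and 0.258% of unchanged variants. The simulated changes followed an exact line on exposure with a fixed dispersion of 0.002. In the real series most variants were called, so these rates may not carry over to them. The class medians were tested on simulated data with a true depletion of 1, and GYM 3p was recovered at 1.05 and 1.00 in the let-7a-1 and miR-374b -1 to 1 series. Variants with no pair, left unchanged there, had medians between -0.031 and -0.0022, yet fell at percentiles 62.45, 7.75, 0.6, 4.9 and 1.1 of random lists in the 5 series (-1 to 1, 1 to 3, each let-7a-1 first, then -1 to 3). A place in the tail of the random lists is therefore no evidence where the median is near 0.

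Alternatives fixed in advance were TMM factors, DESeq2, other minimum counts, the input against the 3 cleaved libraries as 1 group, leaving out each level, 5 added counts, pooled reads in place of means, wobble counted as paired in GYM, each level alone, an input split between levels, and models with no minimum. The backbone correlation without 3p A mismatches at -1 was added after seeing the data, as was the group of 3p A mismatches itself. Gene positions came from GENCODE v29 on GRCh38. The tools were edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1 in R 4.3.3, and numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 in Python 3.11.15.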

Results

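The data are read counts of pre-miRNA variants before and after partial cleavage by DICER, and the question is which base pairs at the randomised positions of the stem make a hairpin a faster or slower substrate. Human let-7a-1 is encoded by MIRLET7A1 on chromosome 9 from 94175957 to 94176036 on the plus strand (GRCh38), an 80-nt microRNA gene that overlaps the lincRNA AL158152.2. miR-374b is encoded by MIR374B on chromosome X from 74218547 to 74218618 on the minus strand, a 72-nt microRNA gene that overlaps the lincRNA FTX on the same strand and MIR374C on the opposite one. Where the random pairs lie in these hairpins is not given in the sources used here. The 16 libraries with 3 random pairs held between 2138662 and 8444521 reads each and listed all 4096 variants. The let-7a-1 -1 to 3 series held 46780415 input reads and 39722557 uncleaved reads over 1041903 of the 1048576 possible variants, with a median of 37 input reads. After the count minimum, 4038, 4075, 4051 and 4083 variants stayed in let-7a-1 and miR-374b -1 to 1 and let-7a-1 and miR-374b 1 to 3, and 792218 in the -1 to 3 series. There were no replicates in any group.

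The first comparison asked which pairs at -1, 0 and 1 went with fast loss from the uncleaved pool. In let-7a-1, all 10 fastest named variants had a C-G pair at -1, 8 had a Watson-Crick pair at 0 and 5 were Watson-Crick paired at all 3 positions. CAC/GUC, with C-G, A-U and a C-C mismatch at -1, 0 and 1, was the fastest, with a fitted depletion of 5.91 (SE 0.43, adjusted p = 6.26e-08 by edgeR); its 1026 input reads stood against 169, 71 and 32 reads at 10, 20 and 30% cleavage. AAC/GUU and CGC/GCG, both fully Watson-Crick paired, followed at 5.38 (SE 0.26) and 5.33 (SE 0.34). The 10 slowest lay between -1.25 and -1.11, and all 10 had a mismatch at -1 and a 5p C at 1; the slowest was CUA/GGG at -1.25 (SE 0.20, adjusted p = 9.17e-05 by edgeR). In miR-374b, 9 of the 10 fastest had C-G at -1 and 6 were fully Watson-Crick paired, led by CGC/GCG at 5.57 (SE 0.90, adjusted p = 2.11e-06 by edgeR). AGC/GCA, CAC/GUG, CGC/GCG and UGC/GCA were among the 10 fastest of both backbones, and no variant was among the 10 slowest of both. Of the 10 slowest in miR-374b, between -1.16 and -1.06, all 10 were mismatched at -1, 8 had no pair at any position and 7 had a 3p A at -1. By edgeR's quasi-likelihood trend, 1722 variants were depleted faster and 1449 slower than the pool in let-7a-1 and 1691 faster and 1614 slower in miR-374b, at an adjusted threshold of 0.05. Testing the input against the 3 cleaved libraries as 1 group in edgeR ended all of these calls, with 0 in both directions in both backbones, and 125 faster and 257 slower in let-7a-1 and 536 and 704 in miR-374b at an unadjusted p under 0.05. That grouping takes the 3 levels as repeats and counts the rise with cleavage as scatter, so its lack of calls cannot judge the trend. Some of the fastest rest on few reads: ACC/GGU in miR-374b, at 5.05 (SE 1.25), had 116 input reads and 3 reads at 30%, where its score was 5.00 (95% counting interval 3.63 to 7.51).

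Base pair states at -1 spread further than those at 0 or 1 in both backbones. C-G was highest at -1, with a mean score of 1.30 (SD 0.68 over the 3 levels) in let-7a-1 and 1.78 (SD 0.61) in miR-374b. Among the other Watson-Crick states, U-A and G-C had 1.19 and 1.00 in let-7a-1 and 1.43 and 1.48 in miR-374b, while A-U reached 0.41 and 0.97. The G-A mismatch lay at 1.03 in let-7a-1, between U-A and G-C. The lowest state at -1 was C-C in let-7a-1, at -0.37 (SD 0.13), and G-A in miR-374b, at -0.38 (SD 0.08). At 0, G-C was highest in both, at 0.78 (SD 0.43) and 1.22 (SD 0.52), and the lowest were G-G at -0.12 (SD 0.06) and G-A at -0.30 (SD 0.08). At 1 the states lay close together: G-G was highest in let-7a-1 at 0.52 (SD 0.31) and A-U in miR-374b at 0.76 (SD 0.37), and C-U was lowest in both, at 0.03 (SD 0.07) and -0.03 (SD 0.07). With reads pooled in place of means, C-U at 1 lay at -0.20 and -0.19, a change of sign in let-7a-1, G-G at 1 at 0.24 in let-7a-1 and A-U at 1 at 0.33 in miR-374b. In let-7a-1 pooling also moved C-G at -1 to 0.83, and G-C and G-G at 0 to 0.51 and -0.21. In let-7a-1 a Watson-Crick pair, a wobble and a mismatch at 1 averaged 0.27, 0.25 and 0.25 over all contexts. In miR-374b they averaged 0.62, 0.17 and 0.17. The SD over levels includes the rise of every effect with cleavage, and it leaves out the error of the shared input.

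**Figure D1:**
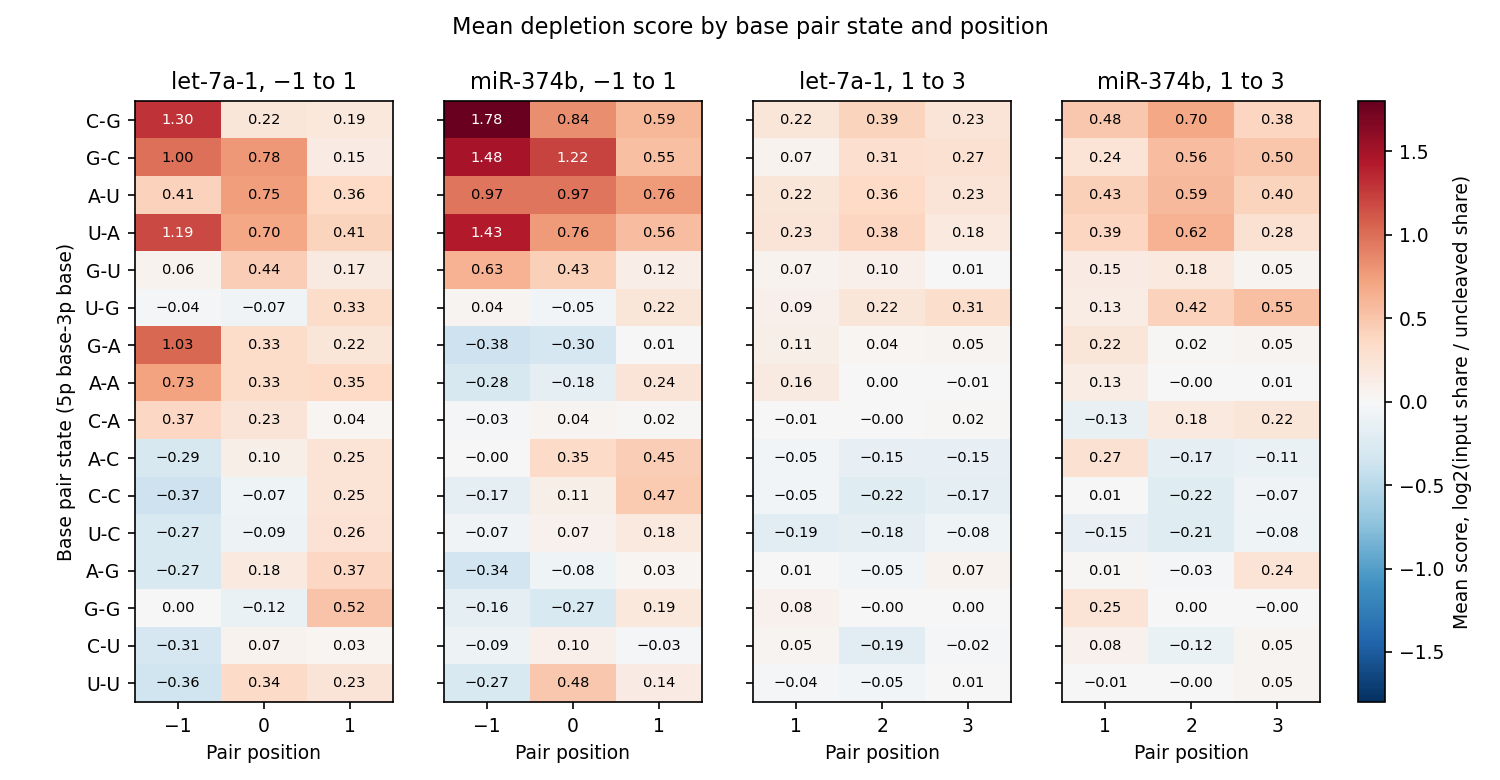
Mean depletion score (log2 of input share over uncleaved share, averaged over 3 cleavage levels) of all variants with each of the 16 base pair states (rows, 5p base first) at each random position (columns), for the 4 series with 3 levels. The C-G state at -1 holds the highest value in both backbones (1.30 and 1.78), and the G-A state at -1 has opposite signs in them (1.03 in let-7a-1 and -0.38 in miR-374b).

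The GYM classes asked whether a G, a pyrimidine and a mismatched A or C at -1, 0 and 1 of the same strand go with fast cleavage. On the 3p strand they did: the 12 GYM variants had a median score of 3.08 in let-7a-1 and 3.36 in miR-374b, and all 12 were called faster in each backbone, also when adjusted over the list alone. On the 5p strand the same elements gave 1.68 and 2.499, again with 12 of 12 called. Replacing the paired 3p G by another Watson-Crick pair lowered the median to 1.78 and 2.55, and replacing the paired pyrimidine by a paired purine lowered it to 2.44 and 2.71. The third element behaved differently. With a Watson-Crick pair at 1 in place of the mismatched A or C the medians were 3.32 and 3.24 (8 variants each), and with a mismatched G or U they were 2.90 and 3.28, against quartiles of GYM 3p itself of 2.67 and 3.31 in let-7a-1 and 3.03 and 3.61 in miR-374b. The class with a Watson-Crick pair at 1 held 1709 input reads in miR-374b, against 32461 for GYM 3p. As a class, a mismatched A or C at 1 had a lower median than a Watson-Crick pair in let-7a-1 and a higher one in miR-374b, without a test. Its members differed, a split singled out after the values were seen: with C-G at -1 and G-C or A-U at 0, C-C at 1 had a mean of 3.93 in let-7a-1 (3.87 to 3.99, 2 variants), above U-A and C-G as the highest Watson-Crick states at 3.45, while C-A and G-A had 2.44 and 2.27. In miR-374b C-C had 3.62 against 3.52 for C-G. In the -1 to 3 series, averaged over random pairs at 2 and 3, it had 1.04 against 1.48 for A-U. Variants paired by Watson-Crick at all 3 positions had medians of 2.20 (64 of 64 called faster) and 2.29 (52 of 52). GYM 3p lay above all 10000 random lists in both backbones, whose highest medians were 2.40 and 2.20. GYM 5p and full Watson-Crick pairing also lay above all of their lists, so this place does not single out GYM 3p. The class depends on Watson-Crick pairing as defined, since counting wobble pairs as paired lowered its median to 1.22 and 1.93. It also lowered GYM 5p to 0.72 and 1.36, and GYM 3p without Y to 0.52 and 1.00, without M to 1.16 and 1.76 and with a mismatched G or U to 1.51 and 1.91; the differences between classes have no replicate test.

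Of the single mismatches, those at 1 had the highest scores. With the other 2 positions Watson-Crick paired, a mismatch at 1 left a median of 1.84 in let-7a-1 and 2.54 in miR-374b, a mismatch at 0 left 1.03 and 1.77, and a mismatch at -1 left 0.04 and 1.03. The 0.04 turned to -0.031 with pooled reads and to -0.011 without the 30% library. Against full Watson-Crick pairing, at 2.20 and 2.29, the mismatch at 1 was lower in let-7a-1 and higher in miR-374b. The gaps were smaller than the SD over the levels (0.97 and 0.83), but that SD includes the rise with cleavage. Each gap kept its sign at every level. At 10, 20 and 30%, full pairing had 1.00, 2.16 and 3.23 against 0.88, 1.81 and 2.82 in let-7a-1. In miR-374b it had 1.606, 2.26 and 2.99 against 1.613, 2.66 and 3.25. The levels share 1 input, so this is no test. In miR-374b full pairing kept 52 of 64 variants at the input minimum, with 12361 input reads. The 160 variants with the mismatch at 1 held 277965. In let-7a-1, 156 of 156 variants with the mismatch at 1 were called faster, 148 of 156 with it at 0, and 67 with it at -1, where 32 were called slower. Adjusted over the list alone, 156, 149 and 67 were faster. In miR-374b the counts faster were 160, 157 and 147 of 160, with 0 slower (160, 157 and 148 adjusted over the list alone). Variants with no pair at any of the 3 positions had medians of -0.23 and -0.53. In miR-374b 783 of 994 of them were slower and 52 faster, but in let-7a-1 476 of 983 were slower and 305 faster. Adjusted over the list alone, the same counts were 783 and 53 in miR-374b and 476 and 305 in let-7a-1.

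**Figure D2:**
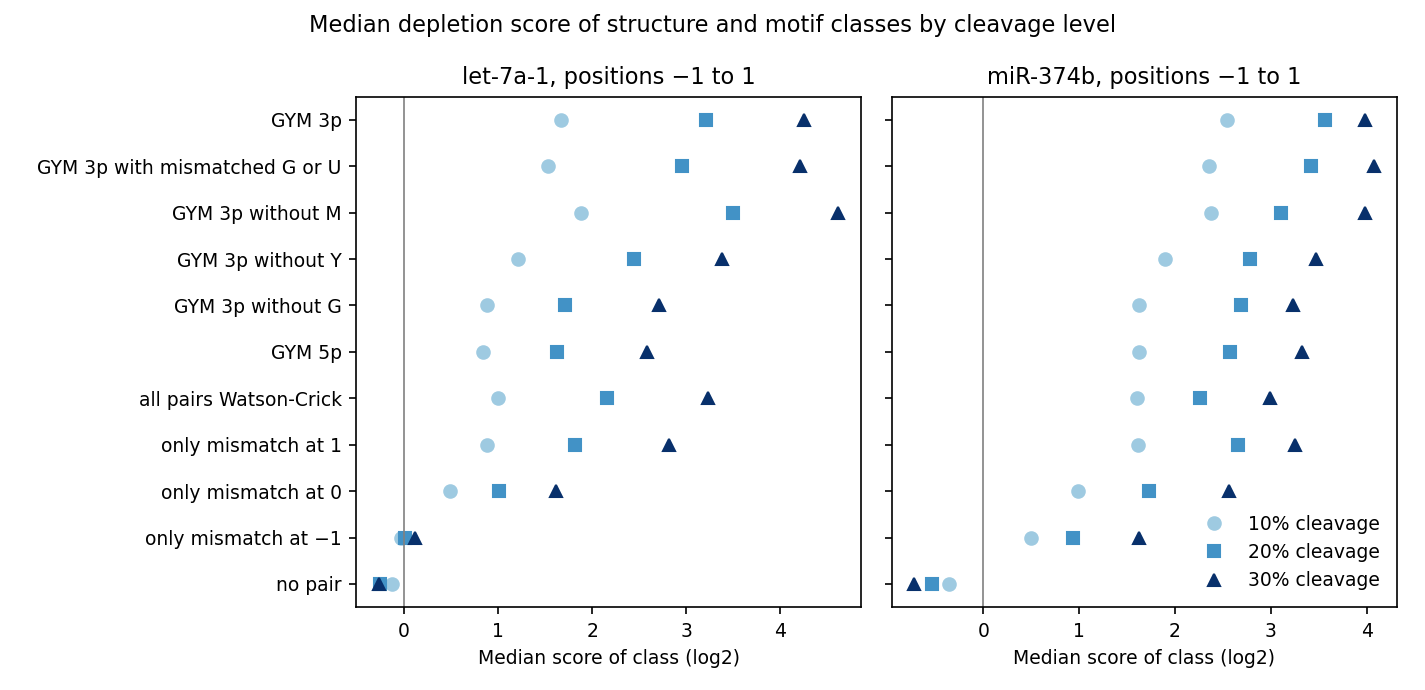
Median depletion score (log2) of structure and motif classes in the series with random pairs at -1 to 1, at 10% (circles), 20% (squares) and 30% cleavage (triangles), each 1 library against the shared input. GYM 3p rose from 1.67 at 10% to 4.25 at 30% in let-7a-1, while variants with a mismatch only at -1 stayed between -0.03 and 0.11 there and reached 1.62 in miR-374b.

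At positions 1 to 3 the question was the same for pairs on the other side of 1. The fastest variants in both backbones combined a C-C mismatch at 1 with Watson-Crick pairs at 2. This held for 8 of the 10 fastest in let-7a-1 and 9 of 10 in miR-374b, all 10 of each having a Watson-Crick pair at 2, and 6 named variants were in both lists (GCC/CGC, CAC/CUG, GAC/CUC, ACC/CGU, GUC/CAC and CUC/CAG). GCC/CGC had a fitted depletion of 3.02 (SE 0.14) in let-7a-1 and 3.40 (SE 0.10) in miR-374b, and GAC/CUC one of 2.76 (SE 0.16) and 3.50 (SE 0.22). The slowest 10 lay between -1.28 and -1.09 in let-7a-1, led by CCC/AUA at -1.28 (SE 0.14), and between -1.05 and -0.998 in miR-374b, led by CCC/ACU at -1.05 (SE 0.06). All 20 were mismatched at 2 and at 3. By edgeR's trend test 1265 variants were faster and 900 slower in let-7a-1, and 2022 and 1464 in miR-374b. The let-7a-1 counts rest on the 30% library, without which they were 390 and 204, DESeq2 called 788 faster and 766 slower, and the input against the 3 cleaved libraries gave 0 calls in edgeR in both backbones, with 107 faster and 89 slower in let-7a-1 and 7 and 22 in miR-374b at an unadjusted p under 0.05. In that grouping the rise with cleavage again counted as scatter. In miR-374b the median fitted depletion of all variants was 0.18 with total counts and 0.04 with TMM factors, a shift of -0.14 to which its calls are relative: TMM factors gave 1775 faster and 1734 slower, and DESeq2 1721 and 1748.

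C-C at 1 was not high in every context. Averaged over all contexts, C-C at 1 had a mean score of -0.05 in let-7a-1 and 0.01 in miR-374b, and the highest states at 1 were U-A at 0.23 (SD 0.18) and C-G at 0.48 (SD 0.33), the lowest U-C at -0.19 (SD 0.08) and -0.15 (SD 0.06), the latter -0.26 with pooled reads. At 2, C-G was highest at 0.39 (SD 0.22) and 0.70 (SD 0.46) and C-C lowest at -0.22 (SD 0.11) in both. In let-7a-1 U-A came close at 0.38, and lay above C-G at 20% (0.37 against 0.34) and 30% (0.64 against 0.63). At 3 the wobble U-G was highest in both backbones, at 0.31 (SD 0.21) and 0.55 (SD 0.36), with G-C next at 0.27 and 0.50. The lowest were C-C at -0.17 (SD 0.07) and A-C at -0.11 (SD 0.04). The gap of U-G to G-C was smaller than the SD over levels, which includes the rise with cleavage. In let-7a-1 U-G lay above G-C at every level, but in miR-374b it lay below at 20% (0.52 against 0.55). In miR-374b pooled reads gave 0.36 for U-G and -0.18 for A-C at 3. With a single mismatch the order was 2, 3 and 1 from slowest to fastest: medians were 0.05, 0.32 and 0.70 in let-7a-1 and 0.32, 0.66 and 1.02 in miR-374b. Without the 30% library those at 2 and 3 were 0.0032 and 0.20 in let-7a-1 and 0.21 and 0.44 in miR-374b, and without the 10% library those at 2 were 0.10 and 0.48. Full Watson-Crick pairing gave 0.63 and 0.86, less than the mismatch at 1 in both backbones by a gap smaller than the SD over levels, and no pair -0.21 and -0.34. The 0.86 of miR-374b was 0.56 without the 30% library and 1.28 without the 10% library, and random lists matched on input reads had a median of 0.51 and a highest of 0.78. In let-7a-1 155 of 156 variants with a mismatch only at 1 were faster, 50 of 156 with it at 2 and 135 of 156 with it at 3; adjusted over the list alone the counts were 155, 44 and 140. In miR-374b they were 160, 146 and 160 of 160 both ways. Full Watson-Crick pairing was called faster in 63 of 63 and 44 of 54 variants, and no pair slower in 530 of 985 and 820 of 998. A mismatched A or C at 1 with pairs at 2 and 3 gave nearly the same median on the 5p strand (0.78 and 1.08) as on the 3p strand (0.74 and 1.06). Variants with A-A, A-C, C-A or C-C at 1 belong to both classes, so the close medians are no comparison of the strands. Without the 30% library the 3p value was 0.47 in let-7a-1, and in miR-374b both were 0.71. Both lay above the 10000 random lists of each series.

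The next comparison asked how far the 2 backbones share these preferences. Scores at 1 to 3 correlated across 4038 variants at r = 0.809 (Spearman 0.783), and those at -1 to 1 across 4017 variants at r = 0.556 (Spearman 0.416), where counting error alone would allow at least 0.967 and 0.994. A departure at -1 to 1, singled out after its values were seen, was an A on the 3p strand mismatched at -1. In let-7a-1 these variants had a mean score of 0.71 (SD 0.81 over 736 variants) against -0.27 (SD 0.42) for other mismatches at -1; in miR-374b the means were -0.23 (SD 0.52 over 764) and -0.16 (SD 0.57). Leaving these variants out raised r to 0.759; among the 732 of them measured in both backbones it was -0.157. By edgeR's interaction test, 505 of the 732 were depleted more in let-7a-1 and 69 more in miR-374b. They were not alike: 218 and 6 of the 252 with G-A, 169 and 10 of the 225 with A-A and 118 and 53 of the 255 with C-A at -1 passed in these directions, with median differences of 1.99, 1.31 and 0.26. Variants with a mismatch only at -1, which include 3p A mismatches, went the other way. Of these, 128 of 156 were depleted more in miR-374b and 3 more in let-7a-1. At most 3 of the 3p A mismatches with Watson-Crick pairs at 0 and 1 were thus called on the let-7a-1 side. GYM 3p variants mostly did not pass the test, with 1 of 12 depleted more in miR-374b and 0 more in let-7a-1. The errors were wide for fast variants: among GYM 3p, CAC/GUC differed by 1.28 (SE 1.03) and GGC/GCA by -0.35 (SE 0.68). Not passing is therefore no evidence of equal depletion.

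Over all variants at -1 to 1, the interaction test called 950 depleted more in let-7a-1 and 1266 more in miR-374b of 4017 tested, and 1199 and 1092 with TMM factors. At 1 to 3 it called 445 and 1130 of 4038, but 745 and 829 with TMM factors, so the share of calls on the let-7a-1 side moved from 28.3% to 47.3%. Without the 30% libraries the calls at 1 to 3 were 17 and 38.

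**Figure D3:**
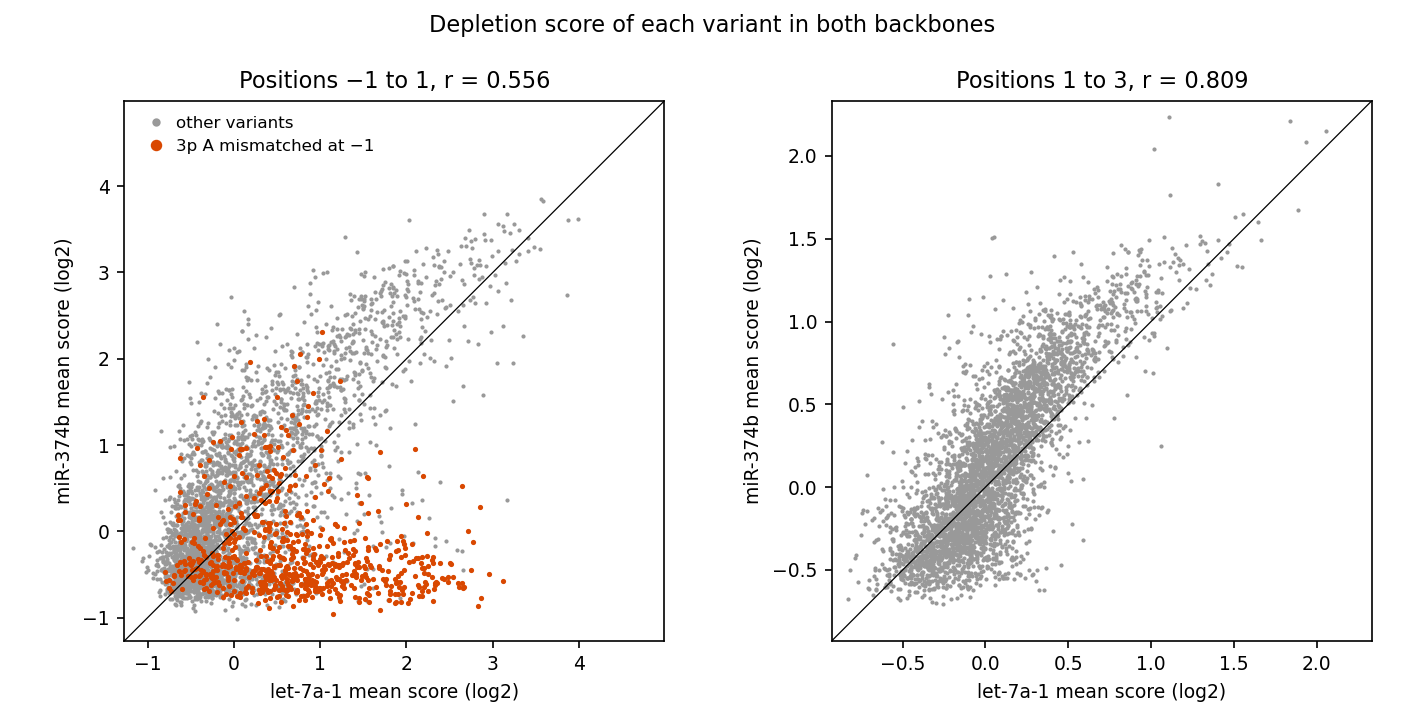
Mean depletion score (log2, average of 3 cleavage levels) of each variant in let-7a-1 (horizontal) and miR-374b (vertical), 1 point per variant, with the line of equal scores, for random pairs at -1 to 1 (left) and at 1 to 3 (right). Variants with a mismatched 3p A at -1 (orange, left) average 0.71 in let-7a-1 and -0.23 in miR-374b.

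The let-7a-1 -1 to 3 series asked the question over 5 pairs at once. Of its 10 highest named variants, 6 had C-G at -1 and 5 were GYM 3p. AUAGC/GCAAU, Watson-Crick paired except for A-A at 1, had 96 input reads and 3 uncleaved reads, a score of 4.55 (95% counting interval 3.17 to 7.07). UCCCC/GGCGA and UCCGC/GCCGA, each with a C-C mismatch at 1 and Watson-Crick pairs elsewhere, had 40 input reads and 0 uncleaved reads each, and the lower bound of the 95% counting interval of their scores was 3.14. Other high variants lacked such pairing: UCACA/AUCUG, with no Watson-Crick pair, had 42 input reads and 0 uncleaved reads, a lower bound of 3.21, and AGAUA/GUGGC, with no pair at all, had 37 and 0, a lower bound of 3.02. The lowest was GGCUC/CCGCU at -1.89 (interval -2.57 to -1.28), and 1 GYM 3p variant, UCGAC/GUAGU, was also among the 10 lowest, at -1.58 (interval -2.19 to -1.02). These are extremes of 792218 variants with a median counting error of 0.31 per score, and the series has no test.

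As classes over 5 pairs, GYM 3p had a median of 0.78 (2899 variants), GYM 5p 0.44, GYM 3p without G 0.40 and without Y 0.47. With a Watson-Crick pair at 1 the median was 1.19, and with a mismatched G or U 0.88, both above GYM 3p with A or C. These medians run over random pairs at 2 and 3. With Watson-Crick pairs at 2 and 3, the median was 2.09 with the mismatched A or C (175 variants). It was 2.05 with a Watson-Crick pair at 1 (88 variants). Counting wobble pairs as paired lowered GYM 3p to 0.26, GYM 5p to 0.12, and GYM 3p without G, without Y, without M and with a mismatched G or U to 0.24, 0.033, 0.60 and 0.48. Full Watson-Crick pairing gave 1.28 (711 variants), and a single mismatch gave 0.07 at -1 (0.026 with pooled reads and 0.034 with 5 added counts), 0.78 at 0, 1.29 at 1, 0.70 at 2 and 1.04 at 3. No pair gave -0.04. Among the 7922 variants in the top 1% by the interval bound nearest 0, a single mismatch at 1 was 26.1 times as frequent as among all, GYM 3p without M 23.0 times, full Watson-Crick pairing 20.8 times and GYM 3p 14.8 times, while a single mismatch at -1 was at 0.103 times. By position, the highest pair states were G-A at -1 (0.62), G-C at 0 (0.29), G-G at 1 (0.22), U-G at 2 (0.25) and U-G at 3 (0.26), and the lowest were C-U (-0.17), U-G (-0.0047), C-A (0.0060), C-C (-0.05) and C-C (0.02). With reads pooled in place of means these were lower throughout, at 0.46, 0.18, 0.07, 0.10 and 0.11 for the highest and -0.20, -0.10, -0.08, -0.12 and -0.05 for the lowest, so that C-A at 1 and C-C at 3 changed sign. With no minimum, U-G at 0 and C-A at 1 changed sign, at 0.0042 and -0.012. C-G at -1, the highest state there in the let-7a-1 -1 to 1 series, had a mean of 0.32 here, below G-A, U-A (0.51) and A-A (0.45). These means also run over random pairs at 2 and 3. In the top 1%, C-G at -1 was 3.88 times and G-A 3.62 times as frequent as among all.

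The libraries of let-7a-1 were compared with each other as the nearest thing to a repeat, although they differ in random positions and cleavage level. The average used here runs over random pairs at positions that the shorter series does not randomise. No ceiling from counting error was computed, so a low r cannot be read as poor repeatability. Averaged over the positions not shared, the -1 to 3 series at 5% cleavage correlated with the -1 to 1 series at r = 0.827 (Spearman 0.818, 4038 variants) and with the 1 to 3 series at r = 0.527 (Spearman 0.535, 4051 variants). Between cleavage levels, which share an input, r ranged from 0.764 in let-7a-1 1 to 3 (10 against 20%) to 0.988 in miR-374b -1 to 1 (20 against 30%). Unchanged pools with a shared input gave 0.549 and 0.512 for the same pairs in simulation, and the covariance exceeded the simulated one by 0.0492 and 1.33. With the input reads split at random between the levels, r was 0.618 and 0.984.

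Sequence models asked how much of the score single bases carry. In the order let-7a-1 and miR-374b -1 to 1, then let-7a-1 and miR-374b 1 to 3, single bases explained 23.9, 5.38, 14.7 and 9.86% of the variance under cross-validation. Adding the pairs raised this to 58.5, 76.7, 59.3 and 70.5%, and adding neighbouring pairs to 74.6, 87.98, 73.98 and 82.1%. In the -1 to 3 series the values were 19.4, 24.8 and 34.3%, with counting error making up 34.7% of the variance.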

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

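The results here are differences between the backbones past the interaction test, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each value is the log2 depletion in let-7a-1 minus that in miR-374b, as estimated in the joint fit. It can depart from the difference of the separate fits. CAC/GUC at -1 to 1, which did not pass, had 5.91 and 4.14 in the separate fits but a difference of 1.28 in the joint one. The group of variants with a 3p A mismatch at -1, the test of a library fault and the counts over other splits of the libraries were chosen after the results were seen. Named variants were picked as extremes of 1 backbone, so the choice itself favours the sign of their differences. A variant among the slowest of 1 backbone tends to be less slow in the other. Without the 30% libraries, 24 of the 34 named differences missed the threshold. No group had 4 libraries, so single samples could not be tested as outliers.

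At -1 to 1, 950 variants were depleted more in let-7a-1 and 1266 more in miR-374b. Of the named variants, the 9 with positive differences were all among the slowest of miR-374b. They were AGG/AAA at 5.28, CAA/AAU at 4.13, AGG/AAG at 3.52, GAC/AAG at 3.04, GUC/AGG at 1.96, GGG/AGU at 1.5, AAU/UAG at 1.499, GAU/UGG at 1.06 and AGU/UGG at 0.75. AGG/AAA had a fitted depletion of 4.20 in let-7a-1 and -1.11 in miR-374b. The 6 with negative differences were among the slowest of let-7a-1: CUA/GGA at -1.32, CAU/CCG at -1.18, CUA/GGG at -1.07, CAA/CCG at -0.99, CUG/GGG at -0.72 and CCG/GGA at -0.57. Of the 35 splits of the 8 libraries into 4 and 4, 8 hold every level once in each group, too few for a share under 0.05. Of these, 1 split, the real one, gave as many calls as the real 2216, and the highest other gave 1869. That other split set the input and 10% libraries of let-7a-1 with the 20 and 30% libraries of miR-374b against the rest. A fixed difference between the 2 pools thus enters its tested term, and the 1869 are no measure of chance.

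The largest of these differences carry a mismatched 3p A at -1. The mean of such variants exceeded that of other mismatches at -1 by 0.97 in let-7a-1 and by -0.07 in miR-374b. A fault of the let-7a-1 -1 to 1 libraries is argued against by the -1 to 3 libraries, where the same contrast was 0.49, and low input by its value of 0.91 among variants with at least 300 input reads. A candidate explanation is pairing shifted by 1 base, in which the 3p A bulges out and the 3p base at 0 pairs with the 5p base at -1: among these variants a Watson-Crick match of that kind raised the let-7a-1 score by 0.46, against 0.03 in miR-374b and 0.30 in the -1 to 3 series, while a Watson-Crick pair in register at 0 added 0.0027 in let-7a-1 and 0.64 in miR-374b. The other direction, with the 3p A pairing to a 5p U at 0, is argued against by a change of -0.12; a biological difference between the hairpins around the random pairs stays open and untested.

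At 1 to 3, 445 variants were depleted more in let-7a-1 and 1130 more in miR-374b. Among the fastest of miR-374b, UUC/CAG differed by -1.71, UAC/CUG by -1.65, UUC/UAG by -0.89 and AAC/CUU by -0.75. Among the slowest of let-7a-1, GUG/CCA differed by -1.02, GUG/UCG by -0.93, CCC/AUA by -0.91, UUG/UCC by -0.80, CCC/AUC by -0.64, CCC/UUU by -0.62, CCA/AUU by -0.58, CCC/AUU by -0.55 and CCC/CUC by -0.51. Among the slowest of miR-374b, UUC/ACC differed by 0.75, AAC/ACC by 0.64, UCC/ACC by 0.61, CUC/ACU by 0.52, CGU/GAU by 0.50 and ACC/ACC by 0.44. Here 2 of the 8 splits that hold every level once in each group gave as many calls as the real 1575, and the highest other gave 2796; 8 splits are again too few for a share under 0.05. That split set the input and 10% libraries of let-7a-1 with the 20 and 30% libraries of miR-374b against the rest, so that a fixed difference between the 2 pools enters its tested term.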

How the results depend on the processing

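No paired analysis was possible because each group held 1 library. All 80 named variants of the 4 series kept their direction and their side of the threshold with TMM factors, with DESeq2, with no minimum and without the 10% library, as did the 68 that a minimum of 300 reads left. Without the 20% library 2 missed the threshold and without the 30% library 5 did; with the input against the 3 cleaved libraries all 80 did. That alternative takes the levels as repeats and gave 0 faster and 0 slower calls in each of the 4 series. The rise with cleavage counts as scatter in it, so its lack of calls cannot judge the trend. DESeq2 called 788 faster in let-7a-1 1 to 3. Leaving out 1 level gave 390 to 1321 faster and 204 to 996 slower there, the lowest without the 30% library. In the same way the interaction calls at 1 to 3 ranged from 17 to 462 on the let-7a-1 side and from 38 to 1208 on the miR-374b side, again lowest without the 30% libraries, and TMM factors gave 745 on the let-7a-1 side. Of the 34 named differences between backbones, 24 missed the threshold without the 30% libraries, 3 without the 20% libraries and 1 with TMM factors. Where not given otherwise, the cause was not tested.

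Counting wobble as paired lowered GYM 3p to 1.22 in let-7a-1 and 1.93 in miR-374b at -1 to 1, and to 0.26 at -1 to 3. At -1 to 3, where depth limits single scores, 5 added counts gave 0.68 for GYM 3p, 1.00 for full Watson-Crick pairing and -0.059 for no pair; pooled reads gave 0.72, 1.22 and -0.060; no minimum gave 0.76 for GYM 3p and -0.035 for no pair. Class medians in the series with 3 levels were held against the SD over the levels, which includes the rise with cleavage and is a lenient measure; leaving out 1 level moved GYM 3p between 2.49 and 3.76 in let-7a-1 and between 3.08 and 3.74 in miR-374b. Between backbones, r at 10% alone was close in the 2 regions, at 0.560 at 1 to 3 and 0.545 at -1 to 1. At 20 and 30% alone it was 0.796 and 0.830 at 1 to 3, and 0.563 and 0.535 at -1 to 1. At -1 to 1 it was 0.759 without 3p A mismatches at -1, which was tried after seeing the data. Pooled reads gave 0.814 and 0.455 for the -1 to 3 series against -1 to 1 and 1 to 3. With no minimum, single bases, pairs and neighbouring pairs explained 13.6, 16.7 and 23.2% at -1 to 3, as counting error then made up 57.0% of the variance. The median of variants with a mismatch only at -1 in let-7a-1 at -1 to 1 changed sign with pooled reads and without the 30% library. Of the named pair states, which carry no test, pooled reads turned the sign of C-U at 1 in let-7a-1 at -1 to 1 and of C-A at 1 and C-C at 3 at -1 to 3, and no minimum that of U-G at 0 and C-A at 1 at -1 to 3.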

Other observations

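The tests of the labelled cleavage percentages were chosen after their results were seen, and the intervals of the medians of neighbouring variants were added after those medians were seen. Shifted pairing of unpaired variants was a hypothesis raised by the named variants themselves; its test on the top 1% was added after the test on all such variants had left it open, and the split by the 3p base at -1 was looked at last, all on the same data.

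The order of G, Y and M on the 3p strand was also placed elsewhere in the 5 pairs of the -1 to 3 series. If the order worked at any place, it may be expected to score alike there. The medians were -0.02 with the G at 0 and 0.07 with the G at 1, against 0.78 with the G at -1, so the higher of the shifted placements differed by -0.71. With the other pairs Watson-Crick, the medians with the G at -1, 0 and 1 were 2.09, 0.52 and 0.95, and with a Watson-Crick pair in place of the mismatch they were 2.05, 0.94 and 1.22. The placement at -1 thus stood apart with and without the mismatch.

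Among the 10 highest variants of the -1 to 3 series, UCACA/AUCUG and AGAUA/GUGGC had no Watson-Crick pair and GCACG/ACUAG had 1. Loss of these single variants stays open: the variants 1 base away had median scores of 1.00, 1.0997 and 1.38, above the bound set beforehand, the 90th percentile of the series at 0.86, but the 95% bootstrap intervals of these medians began at 0.60, 0.71 and 0.75 and so included it. A candidate explanation is pairing shifted by 1 base, each 5p base with the 3p base of the next higher position, but over all variants with no pair in register the mean rose by only 0.27 from 0 to 3 or 4 such matches, wobble included, which leaves it open, and by 0.012 for the shift the other way. Of the 480 such variants in the top 1% by score, 28.5% had 3 or 4 matches against 11.6% of the others, a ratio of 2.45, while the shift the other way gave 0.936. By the 3p base at -1 the rise was 0.71 with A, 0.36 with G, 0.04 with U and -0.02 with C, and no other biological explanation was tested.

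Shares of slow variants rose further than the labelled cleavage allows. If 30% of a pool is cut, the score of an uncut variant can fall to -0.51 at most, yet 18.9% of variants in let-7a-1 and 27.1% in miR-374b at -1 to 1, and 5.63 and 11.8% at 1 to 3, had their whole 95% counting interval beyond that, with the lowest share of any level 2.94% in let-7a-1 1 to 3 at 20%. Counting error is argued against by the 10% of variants most retained at 20% cleavage, picked and scored with separate input reads, whose median at 10 and 30% stood to the limit at -0.23 or below at -1 to 1, at -0.082 or below in miR-374b at 1 to 3 and at -0.049 or below in let-7a-1 at 1 to 3, although there a choice made at 10% gave 0.056 at 20% and 0.016 at 30%. A recovery bias equal at every level stays open, since the median of the most retained variants moved against the limit from 10 to 30% by -0.054 in the series where it moved least and by -0.16 where it moved most. A loss larger than the label may account for it. At 30% and -1 to 1, the 1st percentile of the scores would need a loss of 52.9% of the pool in let-7a-1 and 51.5% in miR-374b. At 1 to 3 it would need 47.8 and 47.4%. These percentiles include counting error and no value measures the loss, so this cannot be told apart from other causes. The exposure behind the fitted depletions, the trend calls and the interaction test rests on the same labels, so an error in them would enter those results.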
